A study of Homo sapiens with 6 samples.

How the data were processed

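Per the labels, 6 libraries were prepared from total RNA of KMS11 cells with a SMARTer mRNA kit, 3 from cells with an shRNA against CRIP1 and 3 from cells with a scrambled shRNA. Groups and replicate numbers were taken from the sample titles. The deposited table gives, for each gene and library, an estimated count, an FPKM value and a TPM value, per the file headers. The estimated counts are expected counts and need not be whole. The submitters' processing notes name HISAT2 2.1.0, Bowtie2 2.2.5, RSEM 1.2.8 and the build GRCh38.p13, without their roles or order, and the annotation is not given in the sources used here. FPKM divides fragments by gene length and library total, TPM is in addition scaled to the same sum in each library, and both were used as deposited by the authors. No strand setting is given, so overlapping and antisense genes cannot be told apart in the counts, and near-identical copies such as the globin pairs, HSPA1A with HSPA1B, and the GAGE genes share reads in a proportion set by the authors' counting.

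Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group at a minimum count of 10, libraries were scaled with TMM, and group alone was fitted with the quasi-likelihood model. Changes are knockdown minus scramble, the SE is the log2 fold change divided by the square root of the F statistic, and p-values were adjusted by Benjamini and Hochberg over the 12612 genes tested, with 0.05 as the threshold. Means and SDs of TPM are over 3 libraries per group. A gene with 0 counts in a group is given as at least a fold against a floor of 3 counts over the group, and one with 1 to 3 counts as a ratio with an exact 95% binomial interval, both of which cover counting error only. Library totals were 16971454 to 18005318 estimated counts, and edgeR's common biological coefficient of variation was 3.33%. Libraries of one group differed by more than sampling noise, with a mean chi-square per gene of 1.62 to 4.15 over genes with at least 20 summed counts, against 99.3 to 104 between groups, so no library was treated as a repeat deposit of another, which does not show that they came from separate cultures.

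Before the data were examined, 42 gene lists were fixed for the proteasome, ubiquitin, autophagy, lysosomes, stress pathways, cell cycle, plasma cell and myeloma genes, metabolism, signalling, RNA quality and other cell types. The 38 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM (counts scaled to library totals) with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation called 0 lists at an adjusted p under 0.05 and 4 at an unadjusted p under 0.05, against 7 with the preset value. That setting also takes p from the few residual degrees of freedom of the 6 libraries, which by itself raises p. For plasma cell identity the estimate was -0.0462, below the preset, yet camera's unadjusted p went from 0.000366 to 0.0187. For ribosomal proteins the estimate was 0.382. A higher p there need therefore not reflect correlation between genes. A member counts as higher or lower by its adjusted p over all genes, and a second count adjusts over the list alone.

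The genes named were also fixed in advance: CRIP1, PSME4, USP7, PSMB5, SQSTM1, MAP1LC3B and TFEB, the 10 largest increases and 10 largest decreases among called genes with a gene symbol, a mean of at least 10 CPM and all 3 values of one group above those of the other, and for each list the 4 members of smallest adjusted p and the member with the largest called fold. Other genes are marked where they were chosen after their values were seen. Some genes that the rule names are not reported here.

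Alternatives fixed in advance were the replicate number as a block, DESeq2 size factors, upper-quartile scaling, the DESeq2 1.42.0 Wald test, no filter on low counts, at least 50 counts in 3 libraries, limma on log2(FPKM + 1) with FPKM of at least 1 in 3 libraries, a prior count of 0.5, a test against a 1.2-fold change, each library left out, and fry, ranks and an estimated correlation for the lists. Added after the data were seen were limma on log2(TPM + 1), removal of a GC trend per library by a loess offset (span 0.5), and removal of genes with at most 3 scramble counts. The loess offset takes out the level of the fitted curve as well as its slope, so it also recentres each library. Genes without a GC value got no offset. Positions, transcript lengths and GC content were taken from GENCODE 29. The fit was tested on simulated data for this comparison with 12612 genes, of which 200 were changed. It recovered 47 of 68 genes changed 1.25-fold, 52 of 66 changed 1.5-fold and 62 of 66 changed 2-fold, with 10 false calls. With a GC trend simulated as well, the same fit made 3104 false calls, and 7 once the trend was removed. Only these 200 genes were changed, about evenly up and down, whereas 9783 of 12612 passed the threshold in the data. The number of false calls need therefore not carry over to the data. No pairing of the libraries by replicate number was detected, as the closing part on processing describes, so the unblocked fit was kept.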

Results

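RNA sequencing was measured in 6 libraries of KMS11, a human line of multiple myeloma, a cancer of antibody-secreting plasma cells. In 3 libraries the cells carried a short hairpin RNA (shRNA) against CRIP1, which encodes a small cysteine-rich LIM domain protein, and in the other 3 they carried a scrambled hairpin. The series title links CRIP1 to the proteasome and to autophagy, so the comparison asks how the transcriptome, and these degradation systems within it, differed once CRIP1 was lowered. The table held estimated counts for 17918 genes. Library totals were 17089392, 17243017 and 16971454 estimated counts for scramble replicates 1 to 3, and 17565071, 18005318 and 17348822 for knockdown replicates 1 to 3. Libraries of one group correlated at 0.995 to 0.996 across genes (Pearson's r of log2 CPM, counts scaled to library totals), against 0.921 to 0.923 between groups, and the leading principal component held 92.8% of the variance. The series describes 3 replicates per group, but the labels do not say that these came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

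CRIP1 was strongly reduced in each library labelled as its knockdown. The gene (NCBI gene 1396, chromosome 14, 105486317 to 105488947, GRCh38 as annotated by GENCODE 29) had 10899, 13322 and 12300 estimated counts in the scramble libraries and 486, 528 and 513 in the knockdown libraries. Its level was 3097 ± 276 TPM (a transcript abundance scaled for gene length and to the same sum in each library; SD, n = 3) in scramble and 130.1 ± 3.71 TPM (SD, n = 3) after knockdown, which is 4.2% of the scramble level. The fitted change was 26.2-fold lower (log2 fold change -4.71, SE 0.06, adjusted p = 6.15e-22 by edgeR's quasi-likelihood test). An exact two-sided permutation test of the 6 TPM values gave p = 0.1, the smallest that 3 against 3 allows. Of its LIM domain relatives, CSRP1 fell by 0.40 on the log2 scale (SE 0.04), while CRIP2 (1.31 against 0.967 TPM) and CSRP2 (3.13 against 2.40 TPM) did not pass the test (adjusted p = 0.401 and 0.484), and the sign of CSRP2 turned without scramble replicate 1. Of the 4 genes tested in this list, CRIP1 included, 0 rose and 2 fell, the same adjusted over the list alone, and 4 were too few for a list test.

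**Figure D1:**
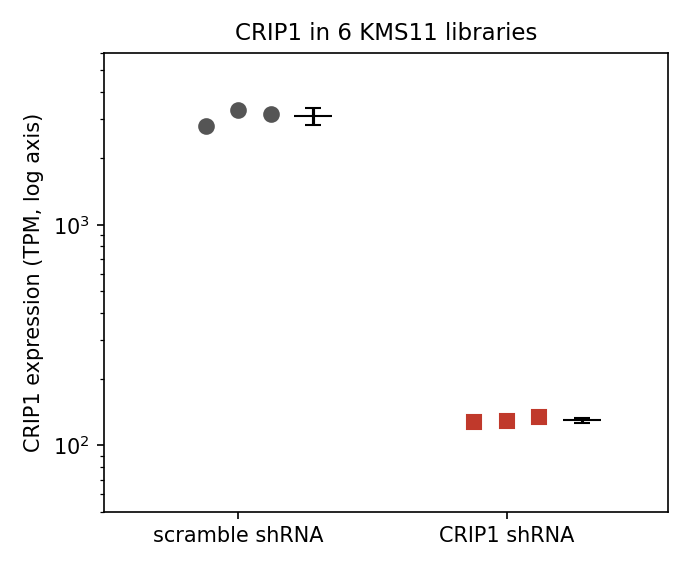
CRIP1 expression in TPM (log axis) in the 3 scramble and 3 CRIP1 shRNA libraries, with single libraries as points and the mean ± SD as a black bar with whiskers. The knockdown mean was 4.2% of the scramble mean.

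The knockdown libraries differed from scramble across most of the transcriptome. The largest increases were in genes with no or few scramble reads. They included ALDH1A2, which makes retinoic acid, the embryonic and fetal globins HBE1, HBG1 and HBG2, the red cell membrane protein RHAG, and the imprinted gene DLK1. With 0 scramble counts, these were at least 568-fold (ALDH1A2), 549-fold (HBG2), 532-fold (DLK1), 505-fold (HBE1), 486-fold (HBG1) and 405-fold (RHAG) higher, taking a floor of 3 counts over the group. HBG1 and HBG2 are near-identical copies, so the split of reads between them is uncertain. GALNT5 had 1 scramble count and a ratio of 1340 (95% counting interval 241 to 53100), and STAT5A, a transcription factor of cytokine signalling, had 2 and a ratio of 850 (235 to 7020). The copper-dependent ferroxidase HEPH rose from 0.06 ± 0.03 to 11.8 ± 0.172 TPM (SD, n = 3 each), and the immediate early factor EGR1 from 0.233 ± 0.107 to 17.0 ± 0.641 TPM.

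Among the genes that fell furthest, IL10, an anti-inflammatory cytokine, went from 82.4 ± 8.96 to 1.37 ± 0.316 TPM (log2 fold change -6.04, SE 0.13). OLFML2B fell from 133 ± 3.26 to 8.69 ± 0.351 TPM (-4.06, SE 0.05). The matrix proteins MATN2 (-3.33, SE 0.06) and LAMB1 (-2.96, SE 0.09) fell, as did the cytochrome P450 CYP1B1 (-3.27, SE 0.11) and TNFRSF13B, the receptor TACI of B lineage cells (-3.26, SE 0.10). CORO1A, an actin-binding protein of leukocytes, fell from 821 ± 10.0 to 101 ± 6.40 TPM (-3.16, SE 0.04). KIF3C, a kinesin, and LBH each fell by 3.09 on the log2 scale (SE 0.09).

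Of 12612 genes tested, 9783 (77.6%) changed at an adjusted p below 0.05 (edgeR), with 4974 higher and 4809 lower, and 50.8% of the changed genes were higher. On log2(TPM + 1), tested with limma, the median of all genes was shifted up by 0.12 rather than 0.01, and 61.4% of changed genes were higher (5531 higher and 3482 lower). With the GC trend removed the balance turned, with a median of -0.08 and 43.2% of changed genes higher (4287 higher and 5635 lower). That correction subtracts the whole fitted curve, its level included, so it also recentres each library. How much of the turn, here and in the lists below, came from GC content rather than from recentring was not tested. Log2 fold changes and counts of members below are from the edgeR fit, and small changes can take their sign from the scaling. In most lists the balance of higher against lower members moved up on log2(TPM + 1) and down with the GC trend removed. At 2-fold or more, 1264 genes were higher and 1017 lower, or 1130 and 1129 with the GC trend removed. The counts were 826 and 472 on log2(TPM + 1), and 562 and 428 on log2(FPKM + 1), where adding 1 also shrinks the folds of genes with low values. Of those 1264 genes, 749 were below 1 TPM in scramble. Without the genes that had at most 3 counts over the scramble libraries, a setting chosen after the data were seen, 1067 were higher and 1017 lower at 2-fold or more.

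Markers of a cell type other than plasma cells separated the groups. Of 9 tested genes of the erythroid list, 8 rose and 0 fell (also 8 adjusted over the list alone; camera adjusted p = 1.59e-05, and adjusted p = 0.237 with an estimated correlation). Their median log2 fold change was 9.82 as fitted and 6.83 with the genes at 0 in scramble set to their bound. HBG2 (185 ± 5.22 TPM), HBA1 (96.4 ± 8.89 TPM) and GATA1, the master transcription factor of red cell precursors (14.4 ± 0.894 TPM; SD, n = 3), had 0 counts in scramble. EPOR, the erythropoietin receptor, named after its value was seen, was at 4.83 and 4.61 TPM in knockdown and scramble and did not pass the test (adjusted p = 0.683). Adult beta-globin, HBB, had 1 count over the 3 knockdown libraries. Across the whole table, 319 genes had at least 5 counts in every knockdown library and at most 3 over the scramble libraries together, against 28 genes the other way. These 319 genes summed to 0.17% of the knockdown TPM.

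Epithelial markers rose in 5 of 9 tested genes and fell in 1 (the same adjusted over the list alone; camera adjusted p = 0.191), led by the keratins KRT18 (27.4 against 0.64 TPM), KRT8 (22.9 against 1.09 TPM) and KRT19 (11.9 TPM, at least 128-fold higher than 0 counts). Fibroblast and endothelial markers went both ways, 2 higher and 3 lower of 5 (the same adjusted over the list alone; adjusted p = 0.766). COL1A2 was at least 213-fold higher and the receptor PDGFRB fell by 2.66 on the log2 scale (SE 0.11), so the list's median was -0.96, its mean 0.71 and its tested direction down. On log2(FPKM + 1) the median was 0.54, with 2 higher and 1 lower. Of 6 mature B cell genes, 2 rose and 4 fell (the same adjusted over the list alone; adjusted p = 0.537), with the complement receptor CR2 higher (1.54, SE 0.07) and SPIB lower (-0.67, SE 0.05). Of 4 myeloid genes, LYZ (3.20, SE 0.28) and CD33 (4.75, SE 0.55) rose, and 2 were not past the threshold, a count that was the same adjusted over the list alone. These 4 genes were too few for a list test, and no T or NK cell marker passed the filter on low counts. Below that filter, CD3D, named after its value was seen, had 19 counts over the knockdown and 0 over the scramble libraries. It is among the 319 genes above, whereas CD3E had 5 and 7 counts.

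**Figure D2:**
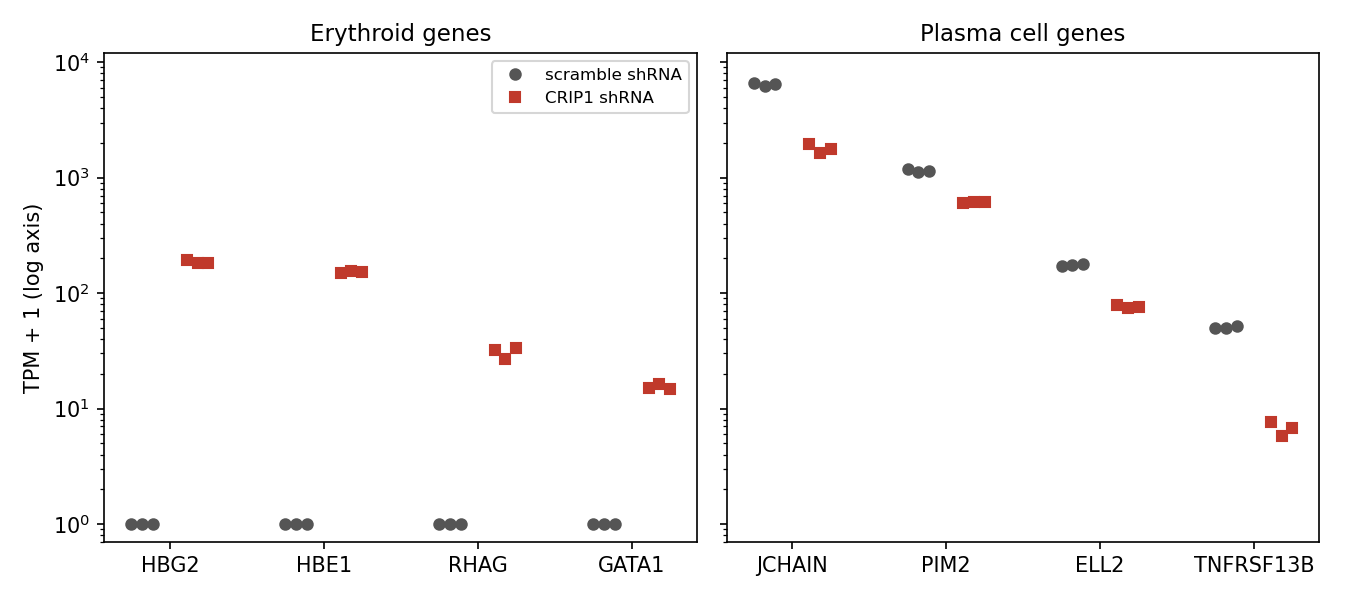
TPM + 1 (log axis) of HBG2, HBE1, RHAG and GATA1 (left) and of JCHAIN, PIM2, ELL2 and TNFRSF13B (right), with 1 point per library. The erythroid genes were at 0 TPM in the scramble libraries (grey circles) and between 14.4 TPM for GATA1 and 185 TPM for HBG2 on average after CRIP1 knockdown (red squares). The plasma cell genes shown were lower after knockdown, while 3 of 16 tested genes of the plasma cell list were higher.

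The proteasome genes moved in both directions. PSMB6, the caspase-like catalytic subunit, fell from 194 ± 3.70 to 82.2 ± 5.95 TPM (SD, n = 3; log2 fold change -1.37, SE 0.06), and PSMB3 fell by 0.60 (SE 0.03), whereas PSMA4 rose by 0.39 (SE 0.04). PSMB5, the subunit that bortezomib inhibits, was at 152 ± 6.84 against 148 ± 4.91 TPM (-0.09, SE 0.05, adjusted p = 0.0795). That value was 0.04 on log2(TPM + 1), and it passed the test as a decrease without CRIP1 shRNA replicate 2 (adjusted p = 0.0427) and with the GC trend removed (0.0198). In the 19S regulatory particle, PSMD2 (-1.18, SE 0.04), PSMD1 (-1.03, SE 0.04) and PSMD13 (-0.91, SE 0.04) fell while the ATPase PSMC2 rose (0.58, SE 0.04). PSME4, the activator PA200, fell from 52.2 ± 0.239 to 33.6 ± 1.82 TPM (-0.77, SE 0.04), the activator subunit PSME1 fell (-0.79, SE 0.05), and NFE2L1, the transcription factor that drives proteasome genes, rose from 253 ± 10.3 to 809 ± 15.7 TPM (1.55, SE 0.03). NFE2L2, a regulator of antioxidant genes, rose by 0.50 (SE 0.04).

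Of 14 genes of the 20S core, 4 rose and 5 fell (camera adjusted p = 0.838). The median was 0.00, the mean -0.11 and the tested direction down, and the tested direction was up on log2(TPM + 1), where 8 rose and 3 fell, whereas 2 rose and 7 fell with the GC trend removed (median -0.09). Of 19 genes of the 19S particle, 5 rose and 12 fell (adjusted p = 0.150), with a median below 0 under each scaling, from -0.32 with the GC trend removed to -0.03 on log2(TPM + 1), where 6 rose and 8 fell. The list of activators and assembly factors also held NFE2L1 and NFE2L2, both higher. Of its 18 genes, 10 rose and 8 fell (adjusted p = 0.819). The median turned from 0.13 to -0.08 with the GC trend removed, where 8 rose and 9 fell, against 10 and 5 on log2(TPM + 1). The immunoproteasome and class I presentation list had 7 higher and 9 lower of 17 (adjusted p = 0.838). There the chaperone CALR fell (-0.99, SE 0.03) while TAPBP (0.90, SE 0.03), ERAP1 (0.70, SE 0.04) and PSMB9 (0.64, SE 0.05) rose, leaving a median of -0.14, a mean of 0.04 and a tested direction of down, or up with the GC trend removed, and 8 rose and 7 fell on log2(TPM + 1). In the ubiquitin list 10 rose and 10 fell of 22 (adjusted p = 0.886), with a median of -0.02 that was positive under upper-quartile (0.02), FPKM and TPM scaling, while 5 rose and 13 fell with the GC trend removed (median -0.12). USP7, a deubiquitinase, fell from 188 ± 1.99 to 135 ± 2.33 TPM (-0.62, SE 0.03) and the E1 enzyme UBA1 fell (-0.66, SE 0.04), while the deubiquitinases UCHL1 (0.60, SE 0.03) and CYLD (0.37, SE 0.03) rose. The counts in these 5 lists were the same adjusted over the list alone, and the libraries that differed in them differed too in erythroid markers (HBG2 at 185 against 0 TPM).

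Most autophagy receptor genes rose. Of 16 receptors, which tie cargo to the autophagosome, 12 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0166, and adjusted p = 0.321 with an estimated correlation). CCPG1, the receptor for turnover of the endoplasmic reticulum (ER), rose from 117 ± 1.66 to 320.4 ± 12.3 TPM (SD, n = 3; 1.26, SE 0.03), with HDAC6 (0.84, SE 0.05), CALCOCO1 (0.64, SE 0.04) and the ferritin receptor NCOA4 (0.52, SE 0.03). SQSTM1, encoding the receptor p62, was the member that fell, from 1337 ± 22.2 to 1101 ± 50.9 TPM (-0.42, SE 0.04). The erythroid markers rose in the same libraries (8 of 9). NCOA4 among the receptors is also used by red cell precursors, but a link between the receptors and these markers was not tested.

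The autophagy machinery was mixed, 16 higher and 11 lower of 37 (the same adjusted over the list alone; adjusted p = 0.461), and its median of 0.09 became -0.02 with the GC trend removed, where 15 rose and 16 fell, whereas 23 rose and 9 fell on log2(TPM + 1) (median 0.21). MAP1LC3B, the LC3B protein of the autophagosome membrane, rose from 146 ± 3.54 to 351 ± 8.96 TPM (1.13, SE 0.04), WIPI1 rose (0.96, SE 0.04) and the fusion protein VAMP8 rose from 2.94 ± 1.05 to 44.1 ± 2.28 TPM, while VMP1 fell (-0.79, SE 0.04). Lysosomal genes were 20 higher and 10 lower of 33 (adjusted p = 0.316), with CTSZ (3.11, SE 0.12) and HEXA (1.02, SE 0.04) higher and CTSH (-1.65, SE 0.07) and CTSC (-0.89, SE 0.04) lower. TFEB, the transcription factor of lysosomal genes, rose by 0.16 (SE 0.07, adjusted p = 0.0345), a call not made by DESeq2 (adjusted p = 0.088) or with no filter (0.0642). It was lost without CRIP1 shRNA replicate 2 (adjusted p = 0.201) or 3 (0.0717) and without scramble replicate 1 (0.0661), 2 (0.0507) or 3 (0.124). Of 17 vacuolar ATPase genes, which acidify lysosomes, 8 rose and 3 fell (adjusted p = 0.306), or 14 and 3 on log2(TPM + 1) and 8 and 5 with the GC trend removed, among them ATP6V1E1 (0.79, SE 0.04), ATP6V1H (0.83, SE 0.05), ATP6V1D (0.70, SE 0.06) and ATP6V0A1 (0.45, SE 0.04), all higher. The lysosomal and ATPase counts were the same adjusted over the list alone, and HBG2 stood at 185 against 0 TPM in these libraries.

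**Figure D3:**
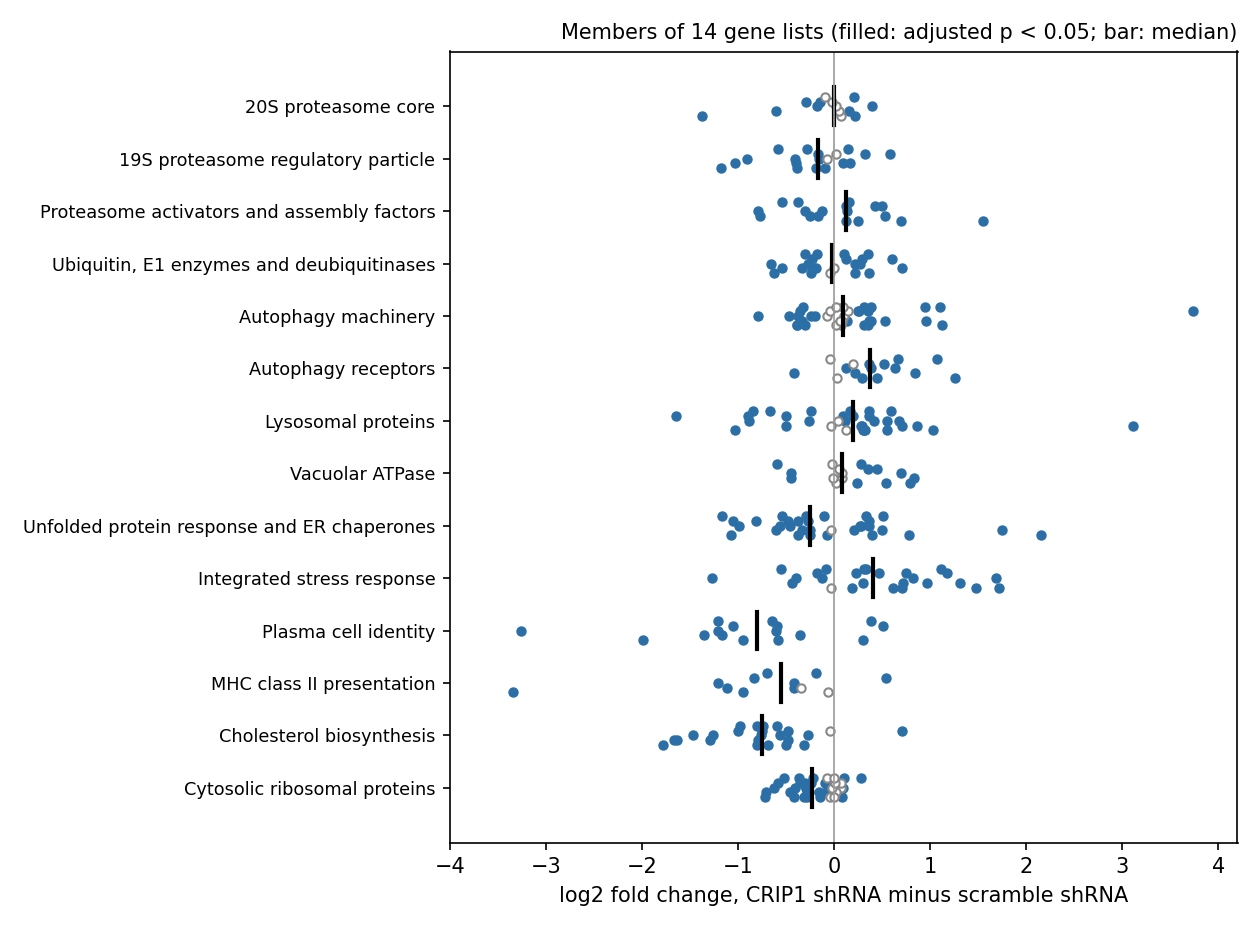
Log2 fold change (CRIP1 shRNA minus scramble shRNA, TMM scaling) of each tested member of the named gene lists, filled where it passed an adjusted p of 0.05 and open where it did not, with list medians as black bars. Members of the 20S core lie on both sides of 0 (median 0.00, or 0.14 on log2(TPM + 1) and -0.09 with the GC trend removed), while the plasma cell (-0.80) and cholesterol (-0.76) medians lie below it.

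Plasma cell genes fell. Of 16 tested genes of plasma cell identity, 13 fell and 3 rose, the same adjusted over the list alone (camera adjusted p = 0.00463, and adjusted p = 0.237 with an estimated correlation). JCHAIN, the joining chain of polymeric antibodies, fell from 6443 ± 223 to 1789 ± 158 TPM (SD, n = 3; -1.99, SE 0.04). TNFRSF13B fell from 49.7 ± 0.903 to 5.70 ± 0.965 TPM, the elongation factor ELL2 by 1.36 (SE 0.04), and the survival kinase PIM2 by 1.05 (SE 0.03) on the log2 scale. The 3 that rose, named after their values were seen, were IRF4 (0.39, SE 0.03), CD38 (0.51, SE 0.06) and TNFRSF17, the receptor BCMA (0.30, SE 0.04). Genes of class II antigen presentation fell as well, 9 lower and 1 higher of 12, the same adjusted over the list alone (adjusted p = 0.0141, and adjusted p = 0.605 with an estimated correlation). They included HLA-DMA (-1.21, SE 0.05), HLA-DPB1 (-1.11, SE 0.04), HLA-DPA1 (-0.95, SE 0.03), the transactivator CIITA (-0.83, SE 0.04) and HLA-DOA (-3.34, SE 0.20), and HLA-DMB, named after its value was seen, rose (0.54, SE 0.05).

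The myeloma oncogene list was split, 7 higher and 10 lower of 18 (the same adjusted over the list alone; adjusted p = 0.316). The gut-homing integrin ITGB7 fell from 1865 ± 39.0 to 867 ± 32.5 TPM (-1.24, SE 0.04), as did the kinase NUAK1 (-1.31, SE 0.05) and the chemokine receptor CCR1 (-1.27, SE 0.06). FGFR3, picked after its value was seen as a gene activated by translocation in KMS11, was at 896 ± 53.3 and 897 ± 34.4 TPM in knockdown and scramble (-0.14, SE 0.04). As plasma cell and class II genes fell, erythroid markers rose in the same libraries, in 8 of 9 tested genes.

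Cholesterol synthesis genes fell almost throughout. Of 24 tested, 22 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 5.74e-06, and adjusted p = 0.237 with an estimated correlation), with a median of -0.76. INSIG1, a sterol-regulated brake on the pathway, fell from 347 ± 3.35 to 111 ± 0.896 TPM (SD, n = 3; -1.78, SE 0.03), and the enzymes LSS (-1.67, SE 0.04), DHCR7 (-1.47, SE 0.05) and MSMO1 (88.9 against 162 TPM) fell. SREBF1, which encodes a transcription factor of lipid synthesis, was the member that rose (0.70, SE 0.05) and was named after its value was seen. In these libraries GATA1 was at 14.4 TPM against 0 in scramble.

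Integrated stress response genes rose in 18 of 26 cases and fell in 7, the same adjusted over the list alone (adjusted p = 0.0223, and adjusted p = 0.605 with an estimated correlation). DDIT3, encoding the transcription factor CHOP, rose from 198 ± 2.70 to 742 ± 25.0 TPM (SD, n = 3; 1.72, SE 0.04), with the pseudokinase TRIB3 (1.68, SE 0.05), the tryptophanyl-tRNA synthetase WARS1 (1.31, SE 0.03) and asparagine synthetase ASNS (1.18, SE 0.04). The unfolded protein response list went both ways, 12 higher and 19 lower of 32 (adjusted p = 0.384). The ER stress sensor ERN1 rose from 26.9 ± 0.760 to 135 ± 2.93 TPM (2.15, SE 0.04) and the co-chaperone DNAJB9 rose (1.75, SE 0.04), whereas the ER chaperones PDIA4 (-1.05, SE 0.04) and CALR fell. Heat shock genes were 5 higher and 12 lower of 21 (adjusted p = 0.129). HSP90AA1 (-0.95, SE 0.03), HSP90AB1 (-0.92, SE 0.03) and HSPB1 (-1.48, SE 0.06) fell, and HSPD1 (0.92, SE 0.03) and HSPA1A (1.98, SE 0.12), which shares reads with a near-identical copy, rose. NRF2 targets, which counter oxidants, were 5 higher and 12 lower of 18 (adjusted p = 0.129), with TKT (-1.30, SE 0.04), TXN (-0.84, SE 0.04), PGD (-0.51, SE 0.03) and ABCC1 (-0.47, SE 0.04) lower. The counts in these 3 lists were the same adjusted over the list alone, and erythroid markers were again higher in the same libraries (HBG2 185 against 0 TPM).

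The glycolytic enzyme gene GAPDH fell from 6161 ± 206 to 3004 ± 147 TPM (SD, n = 3; -1.17, SE 0.04), with ALDOA (-1.24, SE 0.04), TPI1 (-1.12, SE 0.03) and GPI (-1.11, SE 0.04). Over the glycolysis and hypoxia list 16 fell and 7 rose of 27 (adjusted p = 0.129). Of 33 nuclear genes of oxidative phosphorylation, 19 fell and 7 rose (adjusted p = 0.0842), led by the complex I subunit NDUFV2 (-1.54, SE 0.04), and this list passed the threshold with no filter on low counts (adjusted p = 0.0211) and with the GC trend removed (0.0355). On log2(TPM + 1) it had 13 lower and 12 higher, with a median of -0.0017 (adjusted p = 0.258). Of 36 cytosolic ribosomal protein genes, 23 fell and 4 rose (adjusted p = 0.019, and adjusted p = 0.605 with an estimated correlation), with RPS3 and RPL32 each at -0.71. The ribosomal call was lost without CRIP1 shRNA replicate 1 (adjusted p = 0.0635) and on log2(FPKM + 1) (0.088) and log2(TPM + 1) (0.142), where 18 fell and 11 rose. MYC and its targets had 15 lower and 6 higher of 26 (adjusted p = 0.101), with the ribosome assembly genes BOP1 (-1.35, SE 0.05) and NOP16 (-1.09, SE 0.06), spermidine synthase SRM (-1.20, SE 0.05) and NPM1 (-0.58, SE 0.03) lower, and it passed with no filter (0.0294). On log2(TPM + 1) that list had 10 lower and 9 higher (adjusted p = 0.246). The counts in these 4 lists were the same adjusted over the list alone, and RHAG was at 29.7 against 0 TPM in these libraries.

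Cell cycle genes moved in both directions. Of 30 G1/S genes, 15 rose and 7 fell (adjusted p = 0.316), with the ribonucleotide reductase subunit RRM2 rising from 364 ± 14.2 to 900.3 ± 0.966 TPM (SD, n = 3; 1.17, SE 0.03), cyclin E2 (CCNE2) up by 1.58 (SE 0.05), PCNA higher (0.63, SE 0.04) and E2F1 lower (-0.73, SE 0.04). Of 30 G2/M genes, 11 rose and 13 fell (adjusted p = 0.739), KIF2C rising (1.10, SE 0.04) along with CDK1 (0.77, SE 0.04) and NUSAP1 (0.61, SE 0.03) while the checkpoint kinase BUB1 fell (-0.54, SE 0.03). Their median of -0.03 turned positive under upper-quartile, FPKM and TPM scaling, and with the GC trend removed 8 rose and 18 fell. Of 16 cell cycle regulators, 8 rose and 5 fell (adjusted p = 0.531), the inhibitor CDKN2D rising from 6.93 ± 0.427 to 53.3 ± 2.33 TPM (2.80, SE 0.09) and CDKN2C (-0.86, SE 0.04) and CDK6 (-0.78, SE 0.04) falling. Of 28 apoptosis regulators, 15 rose and 10 fell (adjusted p = 0.537), or 11 and 11 with the GC trend removed and 16 and 6 on log2(TPM + 1), with the TRAIL receptor TNFRSF10B (1.35, SE 0.04), BCL2 (0.63, SE 0.04) and MCL1 (0.44, SE 0.03) higher and BID lower (-0.67, SE 0.05). Of 21 p53 targets, 11 rose and 6 fell (adjusted p = 0.531), and the median of 0.16 became -0.03 with the GC trend removed. FDXR rose (1.51, SE 0.10) while CCNG1 (-1.25, SE 0.04) and BTG2 (-1.11, SE 0.04) fell. Of 28 DNA repair genes, 9 rose and 10 fell, or 9 and 9 adjusted over the list alone (adjusted p = 0.766), with a median of -0.06 that was positive on log2(FPKM + 1) and log2(TPM + 1). The counts were 12 higher and 6 lower on log2(TPM + 1), and 8 higher and 16 lower with the GC trend removed. PARP1 fell (-0.83, SE 0.03) along with POLD1 (-0.81, SE 0.05) and EXO1 rose (0.79, SE 0.04). The counts in the other 5 of these lists were the same adjusted over the list alone, and the erythroid genes again separated the libraries (8 of 9 higher).

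Adhesion and cytoskeleton genes changed in mixed directions. The integrin ITGAL fell from 57.3 ± 0.975 to 15.8 ± 0.313 TPM (SD, n = 3; -1.99, SE 0.04), as did the tetraspanin CD9 (-1.69, SE 0.06) and the protease MMP9 (-4.19, SE 0.24), while CXCR4, the receptor that holds plasma cells in bone marrow, rose from 146 ± 5.88 to 344 ± 11.3 TPM (1.10, SE 0.04). Over the adhesion list 8 rose and 15 fell of 24 (adjusted p = 0.129), and the list passed on log2(FPKM + 1) (adjusted p = 0.0373) and log2(TPM + 1) (0.0168). In the cytoskeleton list 9 rose and 19 fell of 29 (adjusted p = 0.129). Vinculin (VCL, 1.87, SE 0.05) and ANXA1 (4.43, SE 0.12) rose and ACTG1 fell (-1.07, SE 0.04). TGF-beta genes were 9 higher and 6 lower of 17 (adjusted p = 0.537), or 6 and 7 with the GC trend removed and 10 and 4 on log2(FPKM + 1), with ID2 (-1.61, SE 0.06), TGFB1 (-1.12, SE 0.05) and SMAD7 (-0.84, SE 0.05) lower and SKIL higher (0.73, SE 0.06). NF-kappaB targets were 9 higher and 6 lower of 20 (adjusted p = 0.900), or 13 and 5 on log2(TPM + 1) and 8 and 7 with the GC trend removed, TNFAIP2 (-1.06, SE 0.04) and CD74 (-0.42, SE 0.03) falling and ICAM1 rising (0.48, SE 0.04). Interferon response genes were 17 higher and 10 lower of 30 (adjusted p = 0.357). IFITM1 rose from 1.45 ± 0.627 to 64.8 ± 3.44 TPM and IFITM3, with 3 scramble counts, had a ratio of 160 (95% counting interval 54.4 to 778), whereas BST2 fell (-0.67, SE 0.04). The counts in these 5 lists were the same adjusted over the list alone, and HBG2 was at 185 against 0 TPM in the same libraries.

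Among groups that can track RNA handling, immediate early genes were 13 higher and 5 lower of 19 (adjusted p = 0.150), with JUN (1.28, SE 0.05) and KLF6 (1.00, SE 0.04) higher beside EGR1. Replication-dependent histone genes, whose transcripts lack long poly(A) tails, were 6 lower and 1 higher of 7 (adjusted p = 0.0818), with H1-2 lower by a log2 fold change of -0.96 (SE 0.05). That list passed with no filter (adjusted p = 0.0166), on log2(TPM + 1) (0.0168) and without CRIP1 shRNA replicate 3 (0.0494). Both counts were the same adjusted over the list alone. The table held 0 mitochondrially encoded genes, so their share was not measured here. In the same libraries 8 of 9 erythroid genes rose.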

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

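CRIP1 stayed lower in each fit run, with a log2 fold change between -4.79 and -4.56, and adding the limma fit on log2(TPM + 1), the GC correction and the removal of genes near 0 in scramble was decided after the data were seen. The number of genes changed ran from 6680 (tested against a 1.2-fold change) to 10306 (no filter), with 9108 by DESeq2 and 9457 to 9786 when a library was left out. The number of genes changed at least 2-fold was 2281, and it was 1519 with at least 50 counts in 3 libraries, where fewer genes were tested. It was 990 on log2(FPKM + 1) and 1298 on log2(TPM + 1), which change the filter, the scaling and the test together. Both also add 1 to each value, which shrinks the folds of low genes. HEPH went from 7.7 by edgeR to 3.6 on log2(TPM + 1), while the abundant CRIP1 went from -4.71 to -4.56. The share of each change of setting in the lower counts was not tested. Of lists, 7 were called with the preset correlation and 6 to 8 with a library left out. Camera with an estimated correlation called 0 (4 at an unadjusted p under 0.05), a setting that also has fewer degrees of freedom. Fry, which does not compare a list with other genes, called 36. Without the genes near 0 in scramble 6 lists were called, since too few erythroid members were left to test. Fry's direction was opposite to camera's for NF-kappaB targets and for fibroblast and endothelial markers. With the replicate number as a block 9816 genes and the same number of lists, 7, were called. Same-numbered libraries did not deviate together (correlations of deviations from the group means 0.0455, -0.00877 and -0.0133), so no pairing by number was detected, which does not exclude one. Over 179 named genes and these settings, 2635 of 2650 values kept direction and side of the threshold, 7 were no longer past it, 2 newly were, and 6 changed sign, all of genes past the threshold under neither setting. These were PSMB5 (-0.09, or 0.0354 on log2(TPM + 1)) and, with a library left out, CD68 (-0.288 to 0.041, positive without CRIP1 shRNA replicate 2), CSRP2 (-0.0845 to 0.578, negative without scramble replicate 1) and ITGAM (-0.0287 to 0.171, negative without CRIP1 shRNA replicate 2 or scramble replicate 1 or 3). The 7 were TFEB, and the 2 were PSMB5, at an adjusted p of 0.0427 without CRIP1 shRNA replicate 2 and 0.0198 with the GC trend removed, and the cause was not tested. Most named genes were chosen for a large fold or a small adjusted p, so their stability does not carry over to other genes. Of all 9783 genes called, 9076 were also called with the GC trend removed. On log2(TPM + 1), with another filter, 7983 were. Depth limits low genes, as for IFITM3, whose 3 scramble counts leave its ratio open from 54.4 to 778.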

Other observations

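Chosen only after the results were seen were the lists of clock genes and of aryl hydrocarbon receptor targets, the tests on HBB, on single knockdown libraries and on plasma cell genes that rose, and the GC correction. Of 17 clock genes tested, 14 rose and 2 fell, also when adjusted over the list alone. Both lists were written for what had been seen, so no list test is given for them. The clock output factors DBP (2.31, SE 0.08) and TEF (2.19, SE 0.08) rose, as did the repressors PER3 (3.20, SE 0.12), NR1D1 (2.12, SE 0.07), NR1D2 (1.78, SE 0.05) and CRY2 (1.03, SE 0.08), all as log2 fold changes. NR1D1 went from 10.6 ± 0.353 to 50.2 ± 4.86 TPM (SD, n = 3). CRY1 (-0.64, SE 0.05) and ARNTL, the activator BMAL1 (-0.21, SE 0.05), fell. TXNIP, a glucose-responsive inhibitor of thioredoxin chosen after its value was seen, rose from 7.86 ± 0.458 to 60.3 ± 2.72 TPM. Targets of the aryl hydrocarbon receptor were 2 higher and 3 lower of 7, the same adjusted over the list alone, and CYP1B1 (-3.27) and CYP1A1 (-2.40, SE 0.10) fell. HBG2 was at 185 against 0 TPM in these libraries, and the labels give no harvest times.

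Of 17918 genes, 319 were read in every knockdown library with at most 3 scramble counts. In cancer-testis and globin families chosen after the values were seen, and not tested for enrichment, these were 6 of 9 GAGE, 1 of 5 XAGE, 10 of 32 MAGE, 1 of 5 PAGE, 2 of 9 SSX, 1 of 9 CT45, 2 of 4 VCX and 7 of 9 globin genes. The GAGE genes are near-identical and share reads. PRAME, chosen after its value was seen, rose from 5.89 ± 0.264 to 90.6 ± 3.82 TPM (log2 fold change 3.83, SE 0.06).

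For the 319 genes read in every knockdown library and almost never in scramble, adult blood or red cell RNA is argued against, since HBB had 1 count over the knockdown libraries beside 1503 of HBG1. A candidate source is a share of erythroid leukaemia cells in the knockdown culture, tested on 30 erythroid genes written down before their values were looked at. Of the 20 that were tested, 10 rose, against 39.4% of all genes (one-sided Fisher's exact p = 0.228), and 7 fell, among them, named after their values were seen, TMCC2 (-1.63), TRIM58 (-0.72) and UROS (-0.65), with a median log2 fold change of 0.18, which leaves it open. The 4 genes below 1 TPM in scramble were all higher, which decides nothing. Genes that low in scramble pass the filter on low counts more readily where they are higher after knockdown. The other 16 were also expressed in scramble, so a small share of other cells could change most of them little. The test therefore had little power, and the genes that fell do not count against such a share. BLVRB at 267 and SLC6A9 at 87.4 TPM, named in the same way, were the most abundant of those that rose by 2-fold or more. A response of the KMS11 cells to the hairpin also stays open, since culture and hairpin cannot be told apart in this design, and reads of HBG1, GATA1 and GAGE1 in 3 of 3 knockdown libraries decide nothing, as the genes were selected that way.

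That 9783 genes, most of those tested, passed the threshold was weighed against chance, GC content and dilution. The real split of the 6 libraries was 1 of 10 splits, too few for a share under 0.05, and the highest other split called 0 genes (edgeR, with 27 at an unadjusted p under 0.05). Each other split put knockdown and scramble libraries on both sides, so the group difference became part of its spread. The few calls there therefore decide nothing. Removing the GC trend left 9922 genes changed, which argues against GC content as the whole cause, although GC and log2 fold change were related across genes (Spearman's rho -0.155, genes not being independent replicates). Dilution of KMS11 RNA by cells without plasma cell transcripts, as the whole cause, is argued against, because 3 plasma cell genes rose while 7 fell by 2-fold or more. That criterion was set after these values were seen, so it was not a test that could have failed. A response to lower CRIP1, an effect of the hairpin itself and a difference between the cultures stay open, as untested.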
